A study of Drosophila melanogaster with 4 samples.

How the data were processed

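Histone H3 trimethylated at lysine 4 (H3K4me3), a modification found at the start of active genes, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos aged 8 to 16 h. Per the labels, the series holds 2 ChIP libraries made with a rabbit polyclonal H3K4me3 antibody and 2 libraries of input DNA, which is the same kind of chromatin sequenced without the antibody step. The flies carried the y, cn, bw and sp markers. Per the labels' protocols, embryos were cross-linked in 1.8% formaldehyde for 15 min.

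The values analysed were those of 1 peak list made for the whole series. Per the submitters' processing notes, CASAVA 1.7.0.2, CASAVA 1.7.0.3, BWA and MACS2 were used with the build BDGP5, and the notes used here give neither their order nor their settings. Per the file headers, positions are on FlyBase release 5, and the source column of the list names MACS as the peak caller. Each deposited peak has a chromosome arm, a start, an end and a score. The score is the authors' own value per peak, and whether it is a p-value, a q-value or an enrichment is not given in the sources used here. It was therefore compared only between peaks of this list, on the deposited values. The sizes of differences, ratios and log2 values of scores depend on that unknown scale, while ranks and the order of medians do not. How the 2 ChIP and 2 input libraries were combined is not given either. The list names no sample, so no value can be assigned to a replicate, no spread between replicates can be given, and the depth of each library is unknown. All intervals and p-values below treat peaks, or blocks of peaks, of 1 list as the unit and measure no biological replication.

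The gene table used for names is based on release 6 of the fly genome, and positions were not moved between releases. No gene was assigned to a peak for this reason. The planned tests of peaks at transcription start sites, of the share of genes with a peak, and of 33 gene lists fixed beforehand were not run. Those lists covered housekeeping, patterning, cell type, sensory and other-tissue genes, and they were fixed before the data were examined, as were the tests and alternatives described next unless stated otherwise.

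Width was counted as end minus start plus 1 base. Density was given as peaks per Mb of the span from the first to the last peak of each sequence, because arm lengths of release 5 were not used here, with exact Poisson 95% intervals. The 6 chromosome arms are 2L, 2R, 3L, 3R, 4 and X, and the autosomal arms compared with X are 2L, 2R, 3L and 3R. The ratio of peak density between X and these arms was given an exact binomial 95% interval. Differences in median score were given bootstrap 95% intervals over peaks (2000 resamples), or over 1 Mb blocks where stated. Blocks allow for the unevenness of peaks along an arm. Shares were given exact Clopper-Pearson 95% intervals, which cover counting error only. The cutoff of 4 kb and the shares of peaks past it were not in the plan fixed beforehand. The relation of width to score was measured across peaks with Pearson's r on log2 values and Spearman's rho, each with 100000 permutations, two-sided. Spacing was compared with 1000 random placements of the same peaks, without overlap, over the same span of each sequence and with the smallest observed gap kept, one-sided. The peaks named by position were fixed by rule as the 10 with the highest score, the 10 widest and the highest of each sequence.

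Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used. The statistics were tested on simulated data. Among 40 simulated lists with randomly placed peaks, 1 passed 0.05 in the spacing test. These lists were placed by the same method as the test uses, so this checks the computation and not whether random placement suits real peaks. A planted X factor of 0.8 on the score was recovered as 0.786 after matching on width. Alternatives were lists without the lowest 25% or 50% of peaks by score, merging of peaks closer than 500 or 1000 bp, other distances for the spacing test, covered length in place of peak number, the mean of log2 scores, and matching on width.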

Results

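H3K4me3 was mapped in 8 to 16 h fly embryos, the period in which the main organs form, from 2 ChIP and 2 input libraries. The deposited outcome was 1 list of 7425 peaks on 15 sequences of FlyBase release 5. The design sets antibody-enriched beside input DNA, and each peak is a region that the authors' peak caller reported with a score. Replicates cannot be compared within this list, and no value below has a replicate error.

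Most H3K4me3 peaks lay on the 6 chromosome arms, which held 6715 peaks or 90.4% of the list. The remaining 710 peaks lay on heterochromatic scaffolds, on unplaced sequence and on the mitochondrial genome. Together the peaks covered 11.9 Mb. The median peak was 1117 bp wide, with quartiles of 501 and 2117 bp and a range from 201 to 17881 bp. Scores ranged from 5.67 to 585.19 with a median of 98.4. In bins of 0.5 on the log2 scale the scores had 2 main modes. The lower mode held 767 peaks at scores from 8 to 11.3, and the upper mode held 1117 peaks at scores from 256 to 362. The least filled bin between them held 337 peaks, at scores from 45.3 to 64. The fall from the lower mode to this bin was not steady. The bin just below it held 433 peaks, and the next lower bin held 342. No peaks overlapped, and the smallest gap between neighbours was 50 bp.

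The highest-scoring H3K4me3 peaks were on the large autosomal arms. The first was at 2L 1609009 to 1614246, with a score of 585.19 and a width of 5238 bp. It was followed by 3R 10564934 to 10566589, with a score of 570.4 and a width of 1656 bp, and by 3L 19824941 to 19827513, with a score of 533.29 and a width of 2573 bp. Of the 10 highest-scoring peaks 4 were on 3R, 3 on 2L, 2 on 2R and 1 on 3L. Their scores were 503.7 or more and their median width was 2456 bp. None of these 10 was on X or on chromosome 4. X held 16.0% of all peaks and chromosome 4 held 1.04%, so their absence among 10 peaks says little. The highest peak of X, at 15031602 to 15033468, scored 501.38, and the highest of chromosome 4, at 1048321 to 1051669, scored 474.81. The highest peak of 2R, at 18297207 to 18307912, scored 524.59 and was 10706 bp wide.

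The widest H3K4me3 regions lay on 2R, 3R, X, 2L and 3L. The widest peak covered 3R 16400546 to 16418426, or 17881 bp, with a score of 393.19. The next were 2L 3452384 to 3470044, with 17661 bp and a score of 363.6, and X 1757295 to 1773737, with 16443 bp and a score of 385.71. X 6179839 to 6195385 held the 4th, with 15547 bp and a score of 281.05. The 10 widest peaks, each of 12161 bp or more, included 3 on 2R, 3 on 3R, 2 on X, 1 on 2L and 1 on 3L. The 10 widest and the 10 highest-scoring peaks shared 0 peaks, although the 2R peak of 10706 bp and the 2L peak of 5238 bp named above were both broad and high-scoring. Across the list 543 peaks, or 7.31%, were 4 kb or wider and these held 26.8% of the covered length. A total of 19 peaks reached 10 kb.

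Wider peaks had higher scores. Across all 7425 peaks Spearman's rho was 0.854 and Pearson's r on log2 values was 0.850. The permutation p was 1e-05 for each, the smallest that 100000 permutations can give. These are correlations across peaks, which are not independent replicates, and 2 coefficients were computed on this set. Width and score come from the same peak call and are not separate measurements. The p therefore does not test a property of the mark. The rho was between 0.829 on chromosome 4 and 0.872 on 3L within the 6 arms. Peaks under 500 bp, 24.9% of the list, had a median score of 12.0, and peaks of 4 kb or wider had a median score of 292.5. Within the top 50% of peaks by score the rho was 0.484. That set was cut on score itself, which can lower rho by narrowing its range, so it does not show a weaker relation among high-scoring peaks.

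**Figure D1:**
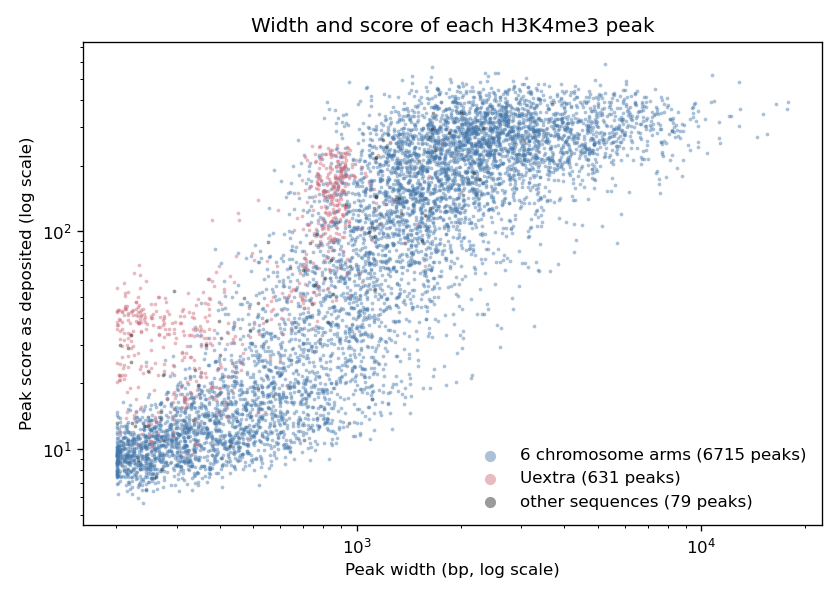
Width in bp (horizontal, log scale) against the deposited score (vertical, log scale) for each of the 7425 peaks, coloured by the kind of sequence. Score climbs with width up to about the upper mode of 256 to 362, and the 631 Uextra peaks lie at the narrow side of the cloud.

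H3K4me3 peaks were spread over every chromosome arm at 51.9 to 63.2 peaks per Mb of span. The lowest density was on 2L, with 51.9 peaks per Mb (95% Poisson interval 49.0 to 54.9), and the highest on 2R, with 63.2 (59.8 to 66.6). X had 53.1 peaks per Mb (50.1 to 56.2) and the 4 large autosomal arms together 56.5. The X to autosome ratio was 0.940, with a 95% interval of 0.882 to 1.00 that includes 1. In complete 1 Mb bins the ratio was 0.944, with a wider block bootstrap interval of 0.788 to 1.11. The Poisson and binomial intervals treat peaks as independent. They are too narrow for comparing arms, since counts in 1 Mb bins varied by more than counting error along the 5 larger arms. Chromosome 4, the small and largely heterochromatic dot chromosome, had 77 peaks and a density of 59.7 per Mb (47.1 to 74.6). That interval overlaps those of the 5 larger arms. Peaks covered 11.1% of the span of 2R, 9.18% of 2L, 8.22% of X and 7.19% of chromosome 4.

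Peak density was uneven within arms. In 1 Mb bins the variance of the number of peaks was between 5.60 times the mean on 2R and 8.86 times the mean on 2L, against a ratio of 1 for peaks placed independently. The densest bin of 2L, from 10 to 11 Mb, held 114 peaks, and the emptiest, from 14 to 15 Mb, held 14. On 2R the bin from 3 to 4 Mb held 107 peaks and on 3R the bin from 5 to 6 Mb held 106. On X the bin from 15 to 16 Mb held 98 peaks and its neighbour from 14 to 15 Mb held 27.

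**Figure D2:**
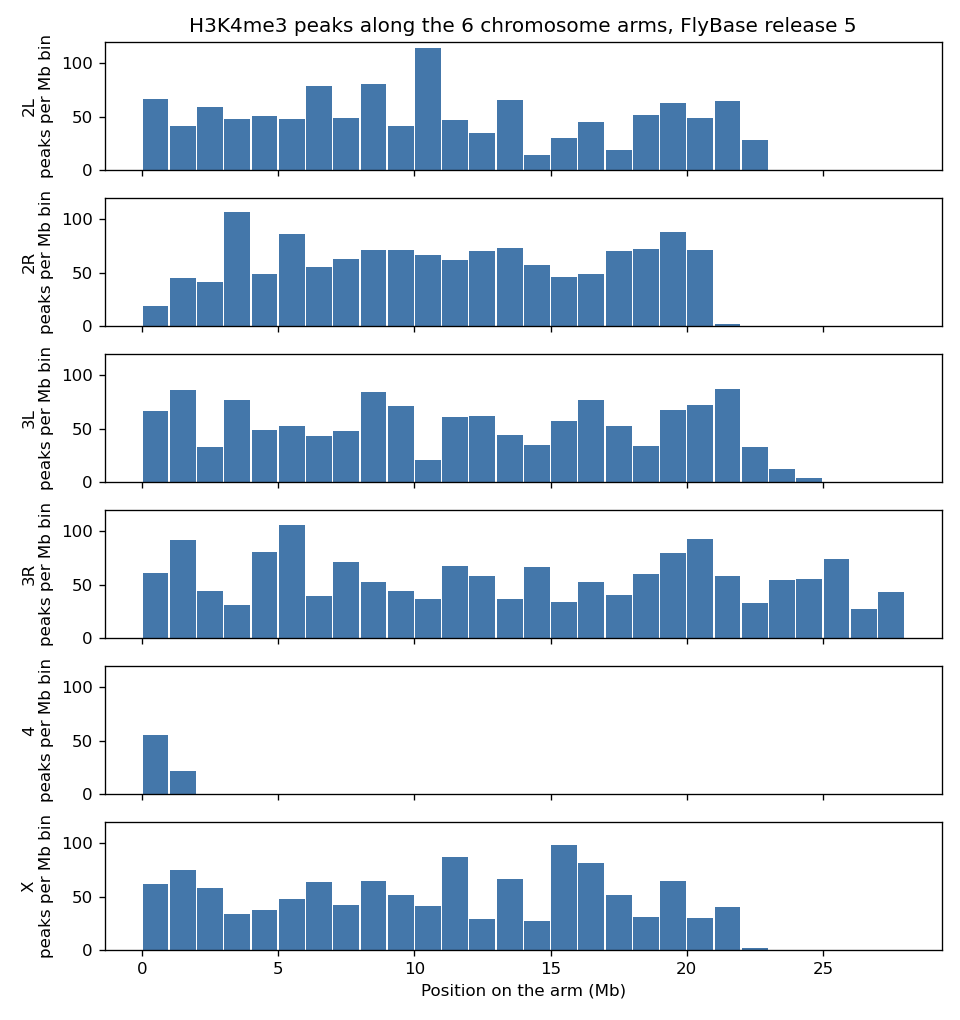
Number of H3K4me3 peaks in each 1 Mb bin (vertical) along the 6 chromosome arms (horizontal, Mb), 1 panel per arm on a common scale. The tallest bar is the 114 peaks of 2L from 10 to 11 Mb, and the last bin of each arm is incomplete.

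Among high-scoring H3K4me3 peaks those on X scored lower than autosomal ones, and a smaller share of X peaks was broad. Over all peaks the median score was 105.89 on X and 106.22 on the autosomal arms, and the difference of -0.33 had a bootstrap 95% interval of -16.1 to 11.4, which holds 0. The upper quartile was 213.19 on X and 249.01 on the autosomal arms, a difference of -35.8 with a block bootstrap 95% interval of -44.7 to -25.7. This quantity was chosen after the data were seen. In the comparison set beforehand, of the top 50% of peaks by score, the median was 211.3 on X and 244.4 on the autosomal arms. That difference of -33.1 had a block bootstrap interval of -42.4 to -25.3. Peaks of 4 kb or wider made up 4.29% of X peaks (51 of 1189, exact 95% interval 3.21 to 5.60) and 9.03% of autosomal peaks (492 of 5449, 8.28 to 9.82). Between the autosomal arms this share lay between 7.96% on 3L and 10.1% on 2L. The share of broad peaks was not among the comparisons set beforehand.

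Chromosome 4 had a score distribution near that of the large autosomes, without their broad peaks. Its median score was 120.85 and its upper quartile 247.59. The widest of its 77 peaks was 3911 bp, so 0 of 77 reached 4 kb, and the exact 95% upper limit of 4.68% lies above the share on X.

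**Figure D3:**
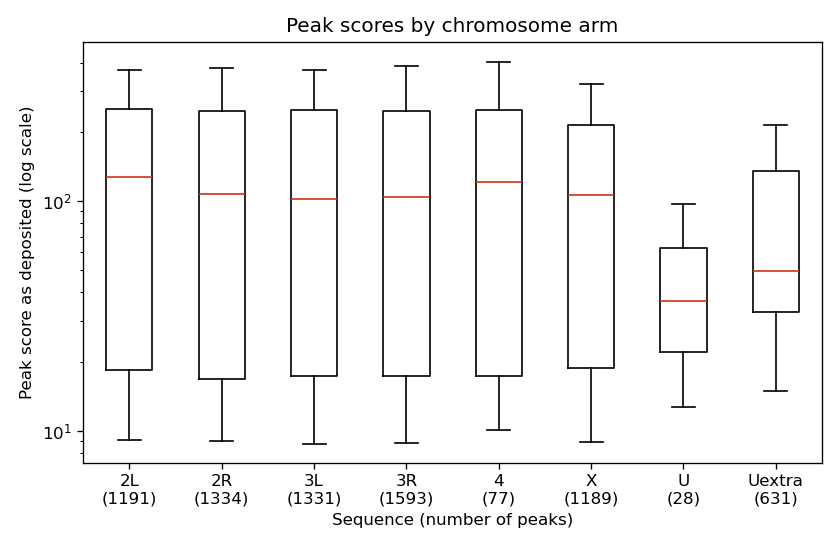
Deposited peak scores (vertical, log scale) by sequence, with the number of peaks under each name. Boxes span the quartiles, red lines are medians and whiskers reach the 5th and 95th percentiles. The upper edge of the X box is at 213.19, below the autosomal arms at 246.35 or more.

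H3K4me3 was also called in heterochromatin. The 6 heterochromatic scaffolds (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet, assembled from sequence near the centromeres and from the Y chromosome) held 50 peaks. Their median score was 114.2 and their median width 1125 bp, close to the 106.6 and 1268 bp of the 6 arms. Their upper quartiles were lower, at 203.9 against 240.4 for score and 1617 against 2241 bp for width. Of the 50 peaks 0 reached 4 kb, with an exact 95% upper limit of 7.11%. The density was low where it could be set beside the arms, at 5.00 peaks per Mb of span on 2RHet (2.80 to 8.24) and 8.00 on 3LHet (4.57 to 13.0). How much of these spans reads could be mapped to was not examined, so the low density cannot be ascribed to the mark. The highest of these peaks was at 3LHet 594552 to 598245, with a score of 384.13 and a width of 3694 bp. At 2RHet 470155 to 471815 the score was 351.43, at 2LHet 167516 to 169169 it was 296.2, and at XHet 60185 to 63248 it was 263.19. The highest of 3RHet, at 1704972 to 1706107, scored 143.43. YHet had a single peak of 335 bp, at 305484 to 305818, with a score of 13.56.

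Unplaced sequence held 659 peaks of a narrower kind. Uextra, a collection of low-quality pieces placed on no chromosome, held 631 peaks with a median width of 504 bp and a median score of 49.6. Its widest peak was 1762 bp and its highest, at 1146932 to 1148181, scored 256.52. U, the other collection of unplaced scaffolds, held 28 peaks with a median width of 515.5 bp and a median score of 36.9, the highest at 9340745 to 9341877 with 218.96. The mitochondrial genome, whose DNA carries no histones, had 1 peak of 273 bp at 8584 to 8856 with a score of 11.05.

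Peaks occurred in close groups. Of 7410 pairs of neighbouring peaks 3154, or 42.6%, were under 1 kb apart. In 1000 random placements the median share was 5.37% and the highest 6.28%, which gives a one-sided p of 0.001, the smallest that 1000 placements can give. The share was 46.3% on the 6 arms alone. Among the top 50% of peaks by score it was 26.3%, against at most 3.76% in random placements. These placements are uniform over each span and take no account of genes or of a marked region called as several peaks. The p above therefore shows only that the spacing was not uniform and does not test a property of the mark. Long stretches without a peak were also more extended than in random placements. The longest on the 6 arms were 2L 16902240 to 17382736, with 480497 bp, 2L 15771064 to 16168515, with 397452 bp, and 3R 23813984 to 24151311, with 337328 bp. These positions were picked after their values were seen. The longest gap in 1000 random placements was 251549 bp, and 22 observed gaps were longer.

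**Figure D4:**
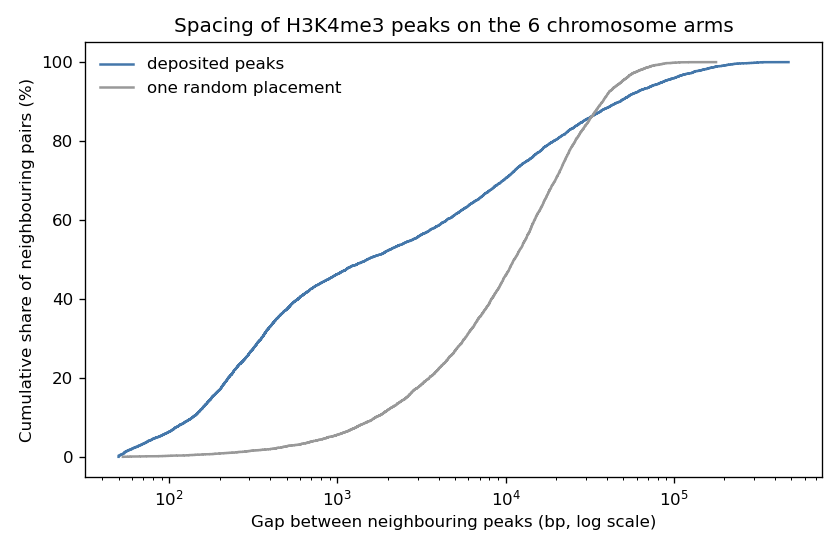
Cumulative share of neighbouring peak pairs (vertical, %) by the gap between them in bp (horizontal, log scale) on the 6 arms, for the deposited peaks and for 1 random placement of the same peaks. The deposited curve is at 46.3% at 1 kb, above the random curve there, and extends to 480497 bp.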

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

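No paired analysis was possible because the deposited list has no column for a replicate. For the same reason, no replicate could be left out. The alternatives set beforehand for transcription start sites and gene lists were not run, since no gene annotation of release 5 was used here. Among 23 alternatives, 16 kept the direction and the side of the threshold or stayed within the limits set for them. A further 4 moved past those limits, and 3 became stronger, with intervals that came to leave out 0. The count of reversed directions was 0, but alternatives for the number of peaks and for density by arm could not be counted as reversed. The number of peaks has no direction, and the main interval of the density ratio includes 1. The number of peaks, 7425 as deposited, depends on the threshold and on merging. It was 3713 without the lowest 50% by score, by construction, 4895 after merging peaks closer than 500 bp, and 4271 after merging those closer than 1000 bp. The median width, 1117 bp as deposited, was 2065, 1450 and 1659 bp in these 3 lists. The X to autosome ratio was 0.940 by number of peaks and 0.835 by covered length, which takes in the widths of the peaks. For covered length in complete 1 Mb bins it was 0.838, with a block bootstrap interval of 0.688 to 1.00 that includes 1. The X minus autosome difference in score was -0.33 for medians over all peaks. It became -33.1 without the lowest 50% by score, -9.91 (-15.0 to -4.59) within matched width deciles, and -35.8 for the upper quartile, each with an interval below 0. The upper quartile, the blocks of 1 Mb, the merging in the arm comparison, the removal of peaks no higher than the mitochondrial one, and the spacing on the 6 arms or without the lowest 25% were added after the data were seen. Spacing remained past the threshold at 500 bp, 1 kb and 2 kb, and rho stayed positive in each list tried, from 0.484 to 0.864. Library depth is unknown, and the bases to which reads could be mapped were not examined. Places without a peak were therefore not detected at the authors' threshold and may carry the mark below it or where reads were not mapped.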

Other observations

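The reading of low scores on Uextra was chosen after its result was seen, and the other tests of explanations below were set down before their results were seen. The ends of the arms nearest the centromere differed in how many peaks they held. The proximal 1 Mb of 3L had 7 peaks (95% Poisson interval 2.81 to 14.4) against 56.3 per Mb over the rest of that arm. The proximal 1 Mb of 2R had 21 (13.0 to 32.1) against 65.2, that of X 22 (13.8 to 33.3) against 54.6, and that of 2L 28 (18.6 to 40.5) against 53.0. On 3R the proximal 1 Mb had 61 peaks (46.7 to 78.4) against 57.0. The Poisson intervals are too narrow for this comparison, since 1 Mb bins varied by more than counting error along every large arm. Of the other complete 1 Mb bins of each arm, 0 of 23 on 3L, 0 of 20 on 2R, 0 of 21 on X, 2 of 21 on 2L and 17 of 26 on 3R held as few peaks or fewer. The median score of the proximal peaks was 222.2 against 104.3 over the rest on 2R, 196.1 against 124.9 on 2L, 188.4 against 101.4 on 3R and 145.3 against 105.1 on X. On 3L it was 28.7 against 101.6. These proximal medians rest on few peaks, only 7 on 3L. They have no interval and were not set against the medians of other bins. How much of each proximal 1 Mb reads could be mapped to was not examined, so low counts there cannot be ascribed to the mark.

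The score of the mitochondrial peak gives a level reached on DNA without histones, but it is 1 value from 1 peak and has no spread. Read depth over the mitochondrial genome and the scale of the score are unknown, so it is not shown to be a background level for chromosomal peaks. At or below the mitochondrial score of 11.05 lay 842 peaks of the list, or 11.3%, among them 827 of the 6 arms and 9 of Uextra.

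X peaks in the upper part of the score range scored lower than autosomal ones, with upper quartiles of 213.19 and 249.01. Within deciles of width the ratio of the X to the autosomal median score had a median of 0.934. Its block bootstrap 95% interval of 0.897 to 0.992 lay only just below 1. This test was set down before its own result was seen, but the use of 1 Mb blocks was added after the data were seen. The median score of X differed from the autosomal one by -9.91 on average over the deciles (-15.0 to -4.59). These values do not settle whether width is the whole cause. A smaller share of X peaks was broad, and widths can still differ within a decile, the widest of which ran from 3617 to 17881 bp. In the simulated data a planted factor of 0.8 was recovered as 0.786, so an interval this close to 1 may lie within the error of matching. Width and score also come from the same peak call. If the score grows with the number of reads, a lower X copy number in a collection of both sexes could lower it, and the X median was the lower one in 9 of 10 deciles, with a median ratio of 0.934 on the deposited values. In an enrichment over input copy number would cancel, and the scale of the score is not known, so this stays open. For comparison, 3R was below the other large autosomal arms in 8 of 10 deciles, but with a ratio of 0.971 and an upper quartile of 247.44 against 249.25. A lower level of the mark on X itself was not tested and stays open, and the labels do not give the sex of the embryos.

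Low-scoring peaks sat beside high-scoring ones. Of 1855 peaks in the lowest 25% by score, 52.3% lay under 1 kb from a peak of the top 50%. The highest share was 6.04% in 1000 random placements of these peaks, which argues against scattered background calls as the source of the whole set. With scores shuffled among the peaks of each sequence the share was 41.2% at the median and 44.3% at the highest, so low scores were nearer to high ones than the grouping of peaks alone gives. A candidate explanation is that edges of marked regions were called apart from their main peak. Separate weakly marked sites near strong ones stay open, and 386 low-scoring peaks were 10 kb or more from any peak of the top 50%, or on a sequence without one.

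The 631 Uextra peaks were narrow for their score. Within deciles of score the ratio of their median width to that of the 6 arms ran from 0.285 to 0.772, with a median of 0.481 (bootstrap 95% interval of this median 0.435 to 0.506). It was below 1 in 10 of 10 deciles, as pieces too short to hold a wide peak could give. Matching on score also argues against their low scores, with a median of 49.6 against 106.6 on the arms, as the reason for the narrowness. At or below the mitochondrial score lay 1.43% of Uextra peaks and 12.3% of those of the 6 arms. The 1 Mb from 28 to 29 Mb held 135 of the 631, with a median width of 260 bp and a median score of 35.5, against 744.5 bp and 80.0 over the rest of Uextra. The sequence of these pieces was not analysed here, so their lengths, repeats in them and other origins stay open, and no biological explanation was tested.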
